A study of Mus musculus with 4 samples.

How the data were processed

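Single-cell RNA was measured in mouse spleen cells of 4 genotypes, with 1 library per genotype. Per the labels, CD117-positive cells were enriched with magnetic beads, captured as a pool and made into libraries with the 10x Chromium X 3' kit, version 3.1, and the molecule was cytoplasmic RNA. Per the submitters' processing notes, the reads were processed with Cell Ranger 5.0.1 on the mm10 genome build. The labels do not say how many animals gave each library, which gene annotation was used, or whether intronic reads were counted. They mention polyI:C, an inducer of interferon, without saying which animals received it or when. The genotypes per the labels were Dnmt3a/Npm1/Nras (here the Nras mutant), Dnmt3a/Npm1/Flt3 (the Flt3 mutant), Dnmt3a/Npm1 and wild type. The labels also list Xpo1, Spen, Elf3, Flcn and Arid1b for the Nras mutant, and Nf1, Arid1a, Cux1, Pik3cd, Kmt2d and Setd1a for the Flt3 mutant.

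The deposited matrices held UMI counts per gene and barcode, as whole numbers and with no normalization. Matrices of 3 libraries were used, each with 28692 features, of which 28416 matched the GENCODE vM21 annotation of GRCm38 by Ensembl identifier. Of the Dnmt3a/Npm1 library only the 12874 barcodes were used; its matrix was not used here. The other libraries held 12983 barcodes (Nras mutant), 8063 (Flt3 mutant) and 11101 (wild type), and the lowest total of a barcode was 500 UMIs in each of them.

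Barcodes with fewer than 500 genes, fewer than 1000 UMIs or more than 10% mitochondrial UMIs were removed. In the Nras mutant, Flt3 mutant and wild-type libraries the gene minimum applied to 1605, 636 and 981 barcodes, the UMI minimum to 1329, 388 and 895, and the mitochondrial maximum to 2164, 909 and 1556. Scrublet, as held in scanpy 1.11.5, was run on each library with a doublet rate of 0.06 and removed 423, 244 and 302 barcodes (3.99%, 3.46% and 3.19%). This left 10173, 6815 and 9158 cells.

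The kept cells of the 3 libraries were scaled per cell and log-transformed, and were clustered together without integration. The clustering used 2000 variable genes, 30 principal components (scikit-learn 1.9.0), 20 neighbours and the Leiden method at resolution 1 (igraph 0.11.9, leidenalg 0.10.2). It gave 35 clusters. Clusters were named from 16 marker lists fixed before the data were examined. A cluster took the name of a list when at least 3 of its markers were detected, each in at least 10% of the cluster's cells, and that list led both the mean marker score and the count of markers among the cluster's 10 leading genes (genes with at least 50 UMIs). The form of this naming rule was settled after the data were seen. The stem and myeloid progenitor lists led the same clusters, so they were merged into 1 class, a choice also made after the clusters were seen. Names carry the ending "-like", and 3 clusters stayed unnamed. With no integration, a cluster held by 1 library alone may be that library rather than a cell type.

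UMIs were summed over the cells of each library and class and scaled to their total as CPM. Levels carry exact Poisson intervals at 95%, shares carry exact Clopper-Pearson intervals, and ratios carry the conditional exact interval. These intervals cover counting error only. Ratios were computed as log2((CPM + 10)/(CPM + 10)). A ratio against 0 UMIs is given as a bound, with the empty group set to 3 counts, and the limit given for a share or level with a count of 0 is likewise 3 counts of the total. With 1 library per genotype no spread between animals can be estimated, so no group test, p-value or count of changed genes was made. Classes were compared only where both libraries held at least 50 cells of the class. The 21 progenitor-like wild-type cells and the 11 monocyte-like Nras mutant cells were under that minimum.

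Named genes followed a rule fixed before the data were examined. Among genes with at least 50 UMIs in the libraries compared, it took the 12 highest and 12 lowest that lay on the same side in both mutants against wild type, ranked by the smaller absolute log2 ratio. For the Nras mutant against the Flt3 mutant it took 8 in each direction. Immunoglobulin and T-cell receptor segments, mitochondrial, ribosomal protein and haemoglobin genes, gene models, Xist and Y-linked genes were left out. The metallothioneins, the HOX and MEIS genes and the genes in the genotype labels were always open to naming, as were members of the gene lists. A few genes that the rule names are not reported here. Outside this rule, genes reported for the makeup of the libraries, for the 21 wild-type progenitor-like cells and for the Y chromosome were chosen after their values were seen.

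Gene lists fixed before the data were examined numbered 18. They covered metallothionein and zinc response, HOX and MEIS, genes named in the genotype labels, stem cell program, granulocyte-monocyte differentiation, RAS-MAPK output, STAT5 targets, interferon response, MHC class II, MHC class I, proliferation, oxidative stress defence, BCL2 family, leukaemia surface antigens, glycolysis, oxidative phosphorylation, dissociation and heat shock, and haemoglobin and erythroid RNA. Each list is given as the median log2 ratio of the members with at least 20 UMIs and as its percentile among 10000 random lists of equal size matched on expression in 20 bins (seed 1). Intervals of a median came from 1000 Poisson draws of the counts. The effect of sharing 1 wild-type library between both mutants was measured in 100 draws in which all 3 libraries of a class were drawn from the same level of each gene, pooled over the libraries.

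Free RNA of dendritic-like cells in the other classes was bounded after the results were seen. Among dendritic markers with at least 100 CPM in dendritic-like cells of a library, the smallest ratio of the other class to dendritic-like cells was applied to the class II genes. Also after the results were seen, the bound on free RNA of progenitor-like cells was applied to granule genes, each matched cluster of dendritic-like cells was compared with wild type on its own, and Flt3 mutant dendritic-like cells were divided by the presence of a Y-linked UMI.

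The steps were tested on simulated data made from the conventional dendritic-like class, Nras mutant against wild type, with 10911 genes. Of 50 genes per simulated fold, 47, 46, 50 and 49 were given the right direction at folds of 2, 0.5, 4 and 0.25. The intervals covered the true ratio for 96.3% of 10711 genes simulated with no difference. The counts were drawn with Poisson error alone, which is the error that these intervals assume. This coverage therefore says nothing of variation between cells, clusters or animals.

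Alternatives chosen in advance were a stricter filter (1000 genes, 2000 UMIs, 5% mitochondrial), no filter, doublets kept, Leiden resolutions 0.5 and 2 for the shares, each library clustered on its own, pseudocounts of 1 and 50 CPM, TMM scaling, the mean of per-cell CPM, cells thinned to 3000 UMIs, a total without haemoglobin, immunoglobulin, mitochondrial and ribosomal protein genes, and list minimums of 0 and 100 UMIs. Added after seeing the data were the same Leiden resolutions for levels, and levels in matched clusters, which are clusters of a class with at least 20 cells in both libraries compared. Y-linked genes were also counted in cells thinned to 5000 UMIs. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.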

Results

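Single-cell RNA libraries of mouse spleen cells were compared between leukaemia genotypes built on Dnmt3a and Npm1 mutation and wild type. Dnmt3a encodes a DNA methyltransferase and Npm1 a nucleolar protein, and both genes are often mutated in acute myeloid leukaemia. The series title concerns metallothionein 1 in this leukaemia. Its design compared malignant populations with normal equivalents to find expression effects kept across mouse models. Each genotype was 1 library, with no replicates. The kept cells carried 166839093 UMIs in 10173 cells of the Nras mutant library, 178928963 in 6815 cells of the Flt3 mutant library and 69604233 in 9158 cells of the wild-type library. Median depths were 13594, 26131 and 6092.5 UMIs per cell, and median genes per cell were 2956, 4081 and 1839. The full matrices held 184244622, 192916468 and 76539347 UMIs. The Dnmt3a/Npm1 library was not analysed here beyond its 12874 barcodes.

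To describe the makeup of each library, cells were assigned to classes by marker genes. The mutant libraries were myeloid and the wild-type library was lymphoid. Progenitor-like cells, which expressed stem cell and myeloid progenitor markers, made up most of the Flt3 mutant library and a smaller part of the Nras mutant library. The largest class of the Nras mutant library was conventional dendritic-like cells. Progenitor-like cells were 21.1% of the Nras mutant cells (95% interval 20.4 to 22.0%), 79.1% of the Flt3 mutant cells (78.1 to 80.1%) and 0.229% of the wild-type cells (0.142 to 0.350%), or 2151, 5392 and 21 cells. Clustering each library on its own gave 16.8%, 78.1% and 0%. Conventional dendritic-like cells were 47.0% (46.1 to 48.0%), 6.43% (5.86 to 7.04%) and 1.33% (1.11 to 1.59%). Neutrophil-like cells were 3.61%, 6.90% and 3.29%. Monocyte-like cells were 0.108%, 2.54% and 2.66%, and plasmacytoid dendritic-like cells were 0.00983%, 2.25% and 2.80%. Of the wild-type cells, 62.4% were B-like, 22.3% T-like, 2.74% NK or ILC-like, 1.65% macrophage-like and 0.262% mast or basophil-like. No B-like or T-like cell was found among the 10173 Nras mutant cells, which allows a share of up to 0.0295% for each. Unnamed clusters held 28.1%, 2.60% and 0.360% of the cells. The wild-type label names cKit-positive progenitors, and Kit RNA was at 77.1, 86.1 and 10.2 CPM in the 3 libraries.

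**Figure D1:**
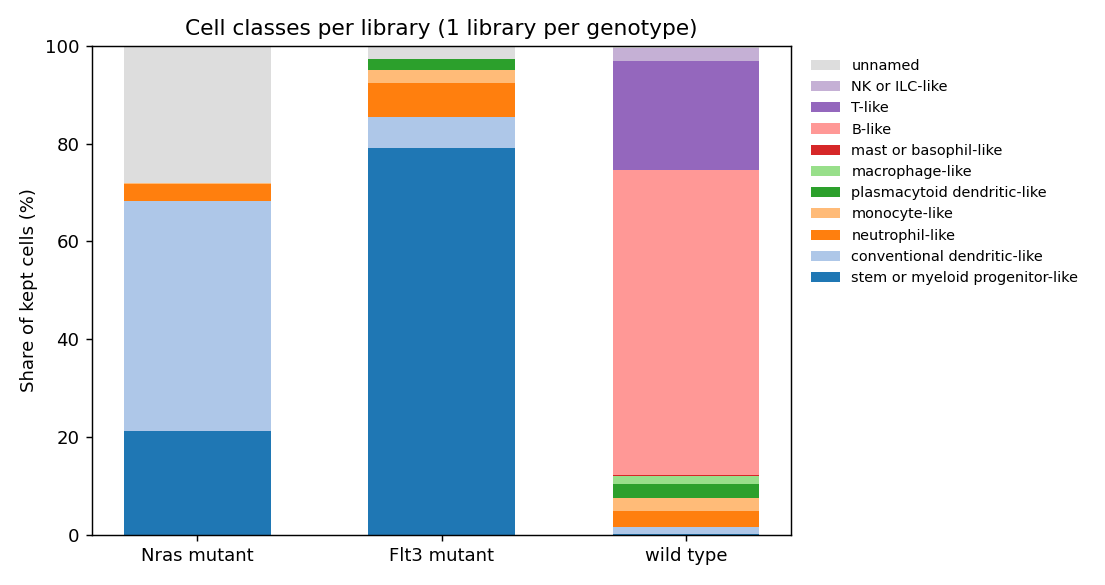
Share of kept cells (%) per cell class, stacked, for the Nras mutant, Flt3 mutant and wild-type libraries, 1 library each and without error bars. Progenitor-like cells reached 21.1% and 79.1% in the mutant libraries and 0.229% in wild type, where B-like cells were 62.4%.

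Over all kept cells, Mt1 and Hoxa9 were far higher in both mutant libraries than in wild type. Mt1 (ENSMUSG00000031765, GRCm38 chromosome 8, 94179082 to 94180327) encodes a metal-binding metallothionein. Mt1 was at 481 CPM (478 to 485) in the Nras mutant, 743 (739 to 747) in the Flt3 mutant and 21.03 (19.97 to 22.14) in wild type. Mt2 (ENSMUSG00000031762, chromosome 8, 94172664 to 94173568) was at 52.7, 50.9 and 7.41 CPM. Mt3 (ENSMUSG00000031760, chromosome 8, 94152607 to 94154146) was at 39.0 CPM in the Nras mutant, and at 0.207 and 0.101 CPM in the other libraries. Hoxa9 (ENSMUSG00000038227, chromosome 6, 52223100 to 52231089), a homeobox gene of early haematopoietic cells, was at 91.3, 96.8 and 0.287 CPM. Hoxa10 was at 46.7, 45.1 and 0.0144 CPM, Hoxa7 at 61.0, 45.8 and 1.59, and Meis1 at 14.4, 19.7 and 1.24. Dnmt3a (ENSMUSG00000020661, chromosome 12, 3806007 to 3914443) was at 18.3 CPM (17.7 to 18.96), 11.4 (10.9 to 11.9) and 30.3 (29.1 to 31.7). Npm1 (ENSMUSG00000057113, chromosome 11, 33152287 to 33163206) was at 876, 1643 and 1108 CPM, and Nras at 34.9, 37.5 and 46.2. Flt3, a receptor of progenitors and dendritic cells, was at 84.4, 27.9 and 10.4 CPM, and Nf1, a brake on RAS, at 26.1, 8.49 and 12.5. Counts of 3' ends cannot show the mutations themselves. These totals follow the cell classes, which differed between the libraries. The wild-type library also stood apart in Gm42418 (3470.3, 2091 and 48719.7 CPM) and Lars2 (75.6, 76.0 and 1324 CPM).

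To compare the leukaemic progenitors with each other, progenitor-like cells of the Nras mutant were set against those of the Flt3 mutant. The Nras mutant cells carried more RNA of the granule protein genes Prg2 and Mcpt8. The Flt3 mutant cells carried more RNA of the prostaglandin-degrading enzyme Hpgd. Mt1, Mt2 and Hoxa9 were at similar levels in both. Mt1 was at 711 CPM (704 to 718) in the Nras mutant and 804 (799.6 to 808) in the Flt3 mutant, a log2 ratio of −0.18. Mt2 was at 58.8 (56.8 to 60.8) and 55.9 (54.8 to 57.1), Hoxa9 at 117.4 (114.5 to 120.2) and 101 (99.3 to 102), Hoxa10 at 55.1 and 46.2, and Hoxa7 at 65.4 and 46.9 CPM. Hoxa5 was 1.06 higher on the log2 scale in the Nras mutant, at 46.2 against 16.9 CPM, and Meis1 was at 15.7 and 20.9 CPM. Dnmt3a was at 16.3 and 11.1 CPM, Npm1 at 1270.2 and 1768, Flt3 at 50.8 and 22.5, and Nf1 at 12.2 and 7.93.

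Among the genes higher in Nras mutant progenitor-like cells, Prg2, which encodes an eosinophil granule protein, was at 347 CPM against 3.55, or 97.8-fold. Mcpt8, a basophil protease gene, was at 1949 against 108 CPM, Pglyrp1 at 651 against 57.8, Ly6k at 356 against 28.4 and Slc4a8 at 603 against 57.5. The class II genes Cd74 (168 against 5.67 CPM), H2-Aa (96.9 against 3.62) and H2-Eb1 (90.8 against 3.48) had log2 ratios of 3.51, 2.97 and 2.90. Class II genes lead the conventional dendritic-like clusters, which were 47.0% of the Nras mutant and 6.43% of the Flt3 mutant cells, and Cd74 was at 18144 and 14021 CPM there. By the dendritic marker with the lowest level in progenitor-like cells (Ifi205), free RNA of dendritic-like cells could give up to 90.3% of the Cd74, 80.6% of the H2-Aa and 79.0% of the H2-Eb1 level of the Nras mutant, so these ratios may hold little RNA of the progenitor-like cells themselves. Lower in the Nras mutant were Hpgd, at 16.7 against 1146 CPM (68.7-fold), and the surrogate light chain gene Igll1, at 0.107 against 102.7. Clu was at 1.86 against 95.7 CPM, Cited4 at 0.3398 against 77.9, Ifitm3 at 17.0 against 218 and Wdr66 at 1.18 against 81.0. Ppic had no UMI in the Nras mutant and 73.7 CPM in the Flt3 mutant, at least 1374-fold lower. The counting interval of the ratio excluded 1 for each of these genes. Before the pseudocount, TMM scaling changed the log2 ratios of this comparison by −0.17.

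The cells of each mutant lay in different progenitor-like clusters. Nras mutant cells were in clusters 7, 12, 20 and 25, and Flt3 mutant cells mostly in clusters 5, 11, 13, 15, 21, 23 and 24. Clusters 7, 12, 20 and 25 held 2145 Nras mutant and 435 Flt3 mutant cells, and within them many of these directions turned. These 435 cells carried Y-linked RNA, at 136 CPM against 0.324 in the other 4957 Flt3 mutant cells, so the ratios within these clusters may not describe most Flt3 mutant progenitor-like cells. Mt1 went from −0.18 to 0.80, Hoxa9 from 0.20 to −0.32, Hoxa10 from 0.21 to −0.86, Hoxa7 from 0.41 to −0.18 and Dnmt3a from 0.31 to −0.10. Ly6k went from 3.25 to −0.31, Clu from −3.16 to 0.11 and Wdr66 from −3.03 to 0.09. Hpgd shrank from −5.44 to −0.27 and Mcpt8 from 4.05 to 0.36. Prg2, Cd74, H2-Aa and H2-Eb1 kept their direction with smaller ratios, at 2.44, 2.80, 2.37 and 2.44. Mt2 was 0.06 over all cells and 1.85 in these clusters. Mt2 turned to −0.08 with TMM scaling and to −0.14 at Leiden resolution 0.5.

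Gene lists were then compared in the progenitor-like cells. The RAS-MAPK output list, which holds feedback genes of RAS signalling, had a median log2 ratio of 0.55 for the Nras mutant against the Flt3 mutant. It lay at percentile 100 of its random lists, with 13 of 15 members higher. Dusp6 was at 41.7 against 13.2 CPM and Etv5 at 5.72 against 0.979. In clusters 7, 12, 20 and 25 the RAS-MAPK median was 0.00249. The stem cell program list had a median of 0.51 (percentile 100), with Gata2 at 62.3 against 9.58 CPM, Erg at 39.7 against 9.75 and Cd34 at 114 against 62.0. Gata2 is also on the mast or basophil marker list. Mcpt8, another marker of that list, is a leading gene of clusters 7 and 20. Those clusters held 848 and 306 Nras mutant cells and 272 and 74 Flt3 mutant cells. Granulocyte-monocyte differentiation had a median of −0.46 (percentile 0), with Irf8 at 37.8 against 107 CPM and Lyz2 at 180.4 against 522. Of its 17 members 11 were lower and 6 higher. Among the higher ones were Mpo, at 2347 against 1311 CPM, and Ctsg, at 7153 against 5874. All 18 oxidative phosphorylation genes were lower in the Nras mutant (median −0.33, percentile 0). MHC class II was at 0.53, STAT5 targets at 0.26, leukaemia surface antigens at 0.35 and genes named in the genotype labels at 0.31, each above percentile 99. BCL2 family was at 0.25 and MHC class I at 0.28. HOX and MEIS was at 0.14 (percentile 97.1), interferon response at 0.13, and dissociation and heat shock at 0.38. Metallothionein and zinc response was at 0.05 (percentile 57.9), oxidative stress defence at 0.03, glycolysis at −0.04, proliferation at −0.11, and haemoglobin and erythroid RNA at 0.10. Within the shared clusters the median turned to −0.22 for the stem cell program, 0.31 for granulocyte-monocyte differentiation and −0.17 for HOX and MEIS. It turned to −0.08 for surface antigens, −0.02 for genotype-label genes, −0.04 for interferon response −0.01 for MHC class I, 0.01 for glycolysis and −0.02 for haemoglobin and erythroid RNA. With TMM scaling, oxidative stress defence turned to −0.04 and metallothionein and zinc response to −0.00332.

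The wild-type library held 21 progenitor-like cells, too few for a comparison with the mutants. Their summed level of Mt1 was 1056 CPM (994 to 1120.3), above both mutants, and 22.2% of those UMIs came from 1 cell. The median cell was below both mutants for Mt1, at 402 CPM in wild type, 588 in the Nras mutant and 667 in the Flt3 mutant. Mt2 was at 477 CPM (436 to 521) and Npm1 at 4312. Hoxa9 was at 12.5 CPM (6.67 to 21.4) and Hoxa10 at 0.964 (0.0244 to 5.37), below both mutants, while Dnmt3a was at 15.4 (8.82 to 25.1) and Meis1 at 13.5. Of the 21 cells, 13 lay in cluster 21. The erythroid genes Car1 (2855 CPM), Klf1 (198) and Gata1 (89.7) were among their transcripts. Gata1 had UMIs in 15 of the 21 cells, against 3 of 2151 Nras mutant and 1 of 5392 Flt3 mutant cells. Elane had UMIs in 3 of the 21 cells, Mpo in 4 and Kit in 15. These 21 cells are thus not a like baseline for the mutant progenitor-like cells. Flt3 RNA had 0 UMIs of 1037102. These genes were chosen after their values were seen.

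**Figure D2:**
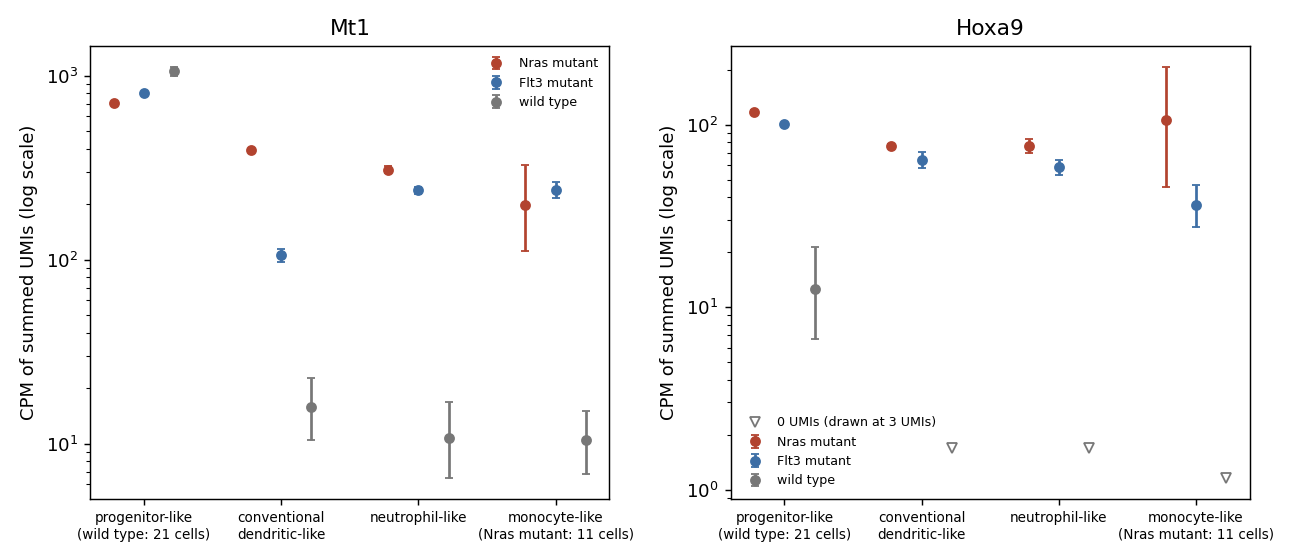
Mt1 and Hoxa9 in CPM of summed UMIs (log axis) per cell class in the 3 libraries, with 95% Poisson bars and open triangles for 0 UMIs, drawn at 3 UMIs. In conventional dendritic-like and neutrophil-like cells both genes were higher in both mutants than in wild type. In monocyte-like cells they were higher in the Flt3 mutant (the Nras mutant had 11 such cells). Mt1 in the 21 wild-type progenitor-like cells was at 1056 CPM, against 711 and 804. Those 21 cells are not a like baseline: the erythroid gene Gata1 had UMIs in 15 of them, against 3 of 2151 and 1 of 5392 mutant cells.

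To ask which differences from wild type were shared by both mutants, conventional dendritic-like cells were compared first. Both mutants had higher RNA of Mt1 and of the HOX genes Hoxa9 and Hoxa10. Both also had higher RNA of Fosb, Fos and Jun, immediate early genes that belong to the dissociation and heat shock list. Both had lower RNA of Apol7c and Ccl5 and of interferon response genes. A Y-linked UMI was found in 47.3% of the Flt3 mutant cells of this class, against 81.7% in the Nras mutant and 73.8% in wild type. Of the 438 Flt3 mutant cells 327 lay in cluster 1 with 1642 Nras mutant cells, so part of them may come from another animal or sample. In the Flt3 mutant cells with and without a Y-linked UMI (207 and 231), Mt1 was at 102 and 109 CPM, Hoxa9 at 83.1 and 45.5 CPM, and the interferon response median against wild type at −0.77 and −1.05. Mt1 was at 394 CPM (389 to 398) in the Nras mutant, 105 (97.2 to 114) in the Flt3 mutant and 15.8 (10.47 to 22.8) in wild type. Mt1 was thus 25.0-fold (17.3 to 37.6) and 6.68-fold (4.58 to 10.1) above wild type. Hoxa9 was at 76.1 and 64.4 CPM with 0 UMIs in wild type, at least 45.0-fold and 38.1-fold higher. Hoxa10 was at 40.6 and 35.3 CPM with 0 wild-type UMIs, at least 24.0-fold and 20.9-fold higher. Hoxa7 was at 62.9, 49.2 and 8.44 CPM in the Nras mutant, the Flt3 mutant and wild type, and Hoxa5 at 31.0, 21.7 and 0.563. Meis1 was at 12.1, 8.71 and 3.38 CPM, and its Flt3 mutant log2 ratio of 0.48 turned to −0.12 in cells thinned to equal depth. Mt2 was at 64.4 CPM in the Nras mutant against 1.13 in wild type, and at 1.54 in the Flt3 mutant. Dnmt3a was at 17.9, 20.999 and 50.7 CPM, with log2 ratios of −1.12 and −0.97. Npm1 was at 754, 725 and 840.5 CPM, and its ratios of −0.15 and −0.21 turned to 0.14 and 0.11 in thinned cells.

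The other genes that were highest in both mutants in this class included the immediate early genes Fosb (515, 488 and 18.0 CPM in the Nras mutant, the Flt3 mutant and wild type), Fos (1219.98, 487 and 26.5), Jun (435, 746 and 64.7) and Ier2 (176, 146 and 25.9). Egr1 was at 98.1, 67.9 and 9.57 CPM, and its Flt3 mutant ratio of 1.99 turned to −0.34 in matched clusters. Fosb, Fos, Jun, Ier2 and Egr1 are all members of the dissociation and heat shock list, whose medians were 1.43 and 1.86 in this class. A response to dissociation was not told apart from other causes for these genes. Egr1 is also a member of the RAS-MAPK output list. Ikzf2, which encodes the transcription factor Helios, was at 112, 84.3 and 1.69 CPM, or 66.3-fold (22.7 to 321) and 49.9-fold (17.0 to 243) above 3 wild-type UMIs. The septin gene Sept3 was at 256, 214 and 18.0 CPM, and Gdpd3 at 75.2, 40.97 and 2.25. The granule protease gene Ctsg was at 37.1 and 29.9 CPM with 0 wild-type UMIs. Ctsg was at 7153 and 5874 CPM in progenitor-like cells of the same mutant libraries, whose free RNA could give up to 30.3% and 86.1% of these levels. For the Flt3 mutant that bound (25.7 CPM) lies within the counting interval of Ctsg.

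Lower in both mutants were Apol7c (1.76, 3.93 and 1080.3 CPM), the chemokine gene Ccl5 (31.9, 27.3 and 2109), Tmem176a (7.64, 9.22 and 374), Tmem176b (7.56, 9.22 and 342) and Adam23 (0.131, 2.56 and 179.6). Hist1h2ap was at 74.0, 78.0 and 1339.8 CPM, Gadd45b at 3.21, 7.85 and 244, and Ltb at 8.15, 5.80 and 242. Il4i1 (6.62, 4.44 and 285 CPM), Fscn1 (4.63, 0.854 and 185) and Fabp5 (18.5, 10.1 and 347) were lower in the main comparison. Under the stricter filter, Il4i1 and Fabp5 had ratios from 0.000691 to 0.43. With each library clustered on its own, Fscn1 had ratios of 0.02 and 0 and Fabp5 of 0.35 and 0.22. Ccl5, Apol7c, Fscn1, Il4i1 and Fabp5 lead cluster 30, which held 46 of 122 wild-type cells, 91 of 4785 Nras mutant cells and 3 of 438 Flt3 mutant cells. In matched clusters the Flt3 mutant ratio of Ccl5 went from −5.83 to −2.19, of Gadd45b from −3.83 to −0.39 and of Il4i1 from −4.35 to −0.60. Cd79a was at 0.0394, 0 and 182 CPM, and it is a gene of B cells, which were 62.4% of the wild-type cells. Ccl5 is also a leading gene of T-like cluster 10 and NK or ILC-like cluster 26, which held wild-type cells alone. In wild-type dendritic-like cells it had 3653 UMIs in cluster 30, against 6 and 66 in clusters 14 and 17. Free RNA of lymphoid cells was not bounded in the wild-type library, so its part in the lower genes was not tested.

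Gene lists gave further shared differences in this class, with the Nras mutant first. The interferon response list had medians of −1.20 and −0.90 (both percentile 0), with 17 and 15 of 18 members lower. Isg15 was at 3.35, 14.2 and 123 CPM and Ifi27l2a at 19.8, 44.4 and 353, whereas Bst2 was at 79.0, 145 and 138. Proliferation was at −1.18 and −1.43, with all 20 genes lower in both, and Top2a was at 65.7, 75.5 and 405 CPM. In matched clusters the proliferation medians were −0.34 and −0.96, but in single clusters they were 0.47, −0.54 and 0.60 in the Nras mutant (clusters 14, 17 and 30) and 0.0065 and −0.18 in the Flt3 mutant (14 and 17), so the lower proliferation was not seen in each cluster. With pseudocounts of 1 and 50 CPM the interferon response median was −2.05 and −0.50 in the Nras mutant and −1.17 and −0.35 in the Flt3 mutant, and the HOX and MEIS median was 1.69 and 0.069, and 2.20 and 0.14. HOX and MEIS was at 0.32 and 0.48 (0.25 and 0.48 with genes of 0 UMIs at their bound), granulocyte-monocyte differentiation at 0.44 and 0.76, and dissociation and heat shock at 1.43 and 1.86, each at percentile 100. Free RNA of progenitor-like cells could give up to 30.3% of Ctsg, 50.7% of Prtn3 and 63.7% of Mpo in the Nras mutant. In the Flt3 mutant it could give up to 86.1%, 90.5% and 90.8%. Elane itself sets the bound in both, so free RNA could give all of it. Other members of the granulocyte-monocyte list were not bounded, so the part of free RNA in its median stays open. RAS-MAPK output was at 0.35 and 0.54, with Dusp6 at 66.6, 50.7 and 18.6 CPM, and the Flt3 mutant median was 0 without a UMI minimum. MHC class I was at −0.47 and −0.35 (percentiles 1.41 and 2.16), with H2-K1 at 713, 793 and 1626 CPM. Metallothionein and zinc response was at 0.19 and 0.13 (percentiles 98.8 and 93.2). MHC class II was at 0.24 and 0.19, STAT5 targets at 0.10 and 0.27, surface antigens at 0.06 and 0.05, and glycolysis at 0.10 and 0.05. The stem cell program was at 0.05 and 0.14 and turned to −0.13 and −0.32 in matched clusters. Oxidative stress defence (−0.08 and −0.09), oxidative phosphorylation (−0.16 and −0.05) and genotype-label genes (−0.07 and −0.01) turned positive with TMM scaling. BCL2 family was at −0.08 and 0.02, and the first turned to 0.12 with TMM scaling. Haemoglobin and erythroid RNA was at 0.82 in the Nras mutant and turned to −0.73 in matched clusters.

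Matched clusters, pooled, kept the direction of the named shared genes in both mutants, except for Egr1 in the Flt3 mutant (−0.34). For the Nras mutant they include cluster 30, with 46 of the 94 wild-type cells and 91 of the 1194 Nras mutant cells, so the pooled ratios still hold a difference in makeup. Within single clusters the log2 ratio of Ccl5 was −0.49, −2.63 and −1.52 in the Nras mutant (clusters 14, 17 and 30) and that of Apol7c −7.22, −4.95 and −3.19. Fabp5 turned to 0.25 in cluster 14 and 0.42 in cluster 30, Il4i1 to 0.05 and Fscn1 to 0.01 in cluster 14, and in the Flt3 mutant Fabp5 turned to 0.29, Fscn1 was at 0 and Egr1 at −0.93 in cluster 14. The other named genes kept their sign in each cluster, but for several of the lower genes the counting interval of the fold included 1. Among these were Ccl5 in cluster 14 (0.22 to 1.40 in the Nras mutant, 0.16 to 1.73 in the Flt3 mutant) and Hist1h2ap in cluster 14 (0.35 to 1.67 and 0.17 to 1.33). Gadd45b was another, in clusters 14 and 17 of the Flt3 mutant. The log2 ratio of Mt1 was 3.19, 4.53 and 1.94 in the Nras mutant and 2.28 and 2.61 in the Flt3 mutant, and its interval excluded 1 in each cluster. Mt1 was 17.7-fold higher in the Nras mutant (11.6 to 28.7; clusters 14, 17 and 30, with 1194 and 94 cells) and 11.3-fold higher in the Flt3 mutant (6.04 to 24.0; clusters 14 and 17, with 97 and 48 cells). Hoxa9 was at least 39.2-fold and 26.8-fold higher there, and the interferon response medians were −0.80 and −0.65, and from −1.02 to −0.35 in single clusters. Flt3 mutant cells of clusters 14 and 17 carried Y-linked RNA at 74.6 and 131 CPM, against 0.324 in most Flt3 mutant progenitor-like cells. Part of these 97 cells may thus come from another animal or sample. Both mutants shared 1 wild-type library. Of 10172 genes 83.3% lay on the same side in both mutants, and draws without a difference gave 83.3%. The shared direction over all genes was thus no more frequent than a shared control gives. The smallest ratio named was 1.99 in size, against 1.02 for the largest in those draws. Those draws hold counting error alone, and the named genes were picked as the most extreme. The comparison therefore says nothing of differences between animals, libraries or cell makeup. TMM scaling changed the log2 ratios before the pseudocount by 0.28 for the Nras mutant and 0.18 for the Flt3 mutant, and median depths were 14803, 11824.5 and 13846 UMIs.

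Between the mutants, conventional dendritic-like cells of the Nras mutant had higher RNA of Mt1, Mt2 and Mt3, while the metallothionein and zinc response list as a whole had a median of 0.0088 (percentile 50.6), with 7 members higher and 7 lower. Mt3 was at 83.9 against 1.20 CPM, Mt2 at 64.4 against 1.54 and Mt1 at 394 against 105, with log2 ratios of 3.07, 2.69 and 1.81. In matched clusters the ratios of Mt3, Mt2 and Mt1 were 1.997, 1.65 and 1.14. Serpine2, which encodes a protease inhibitor, was at 95.3 against 0.854 CPM, Phgdh at 104 against 7.17, Tgfbi at 155 against 22.5 and Rgs1 at 121 against 16.7. Fkbp5 was at 149 against 25.6 CPM and Pex11a at 50.3 against 4.10. Lower in the Nras mutant were the heat shock genes Hspa1b (1.33 against 236 CPM) and Hspa1a (6.52 against 288) and Cd209a (19.5 against 102). Elane was at 4.17 against 43.9 CPM, 0.157% and 0.438% of its level in progenitor-like cells, and at 923 against 9118 CPM over the whole libraries, so this difference was not told apart from free RNA of progenitor-like cells. S100a4 was at 89.4 against 268 CPM, Abcg3 at 7.27 against 37.9, Phf11a at 49.3 against 143 and Ms4a4c at 6.22 against 29.9. The RAS-MAPK output list was at 0.34 (percentile 100) and interferon response at −0.34 (percentile 0), which was −0.04 in matched clusters. Haemoglobin and erythroid RNA was at 1.17 and turned to −0.01 in matched clusters. HOX and MEIS was at 0.03 and BCL2 family at 0.22.

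**Figure D3:**
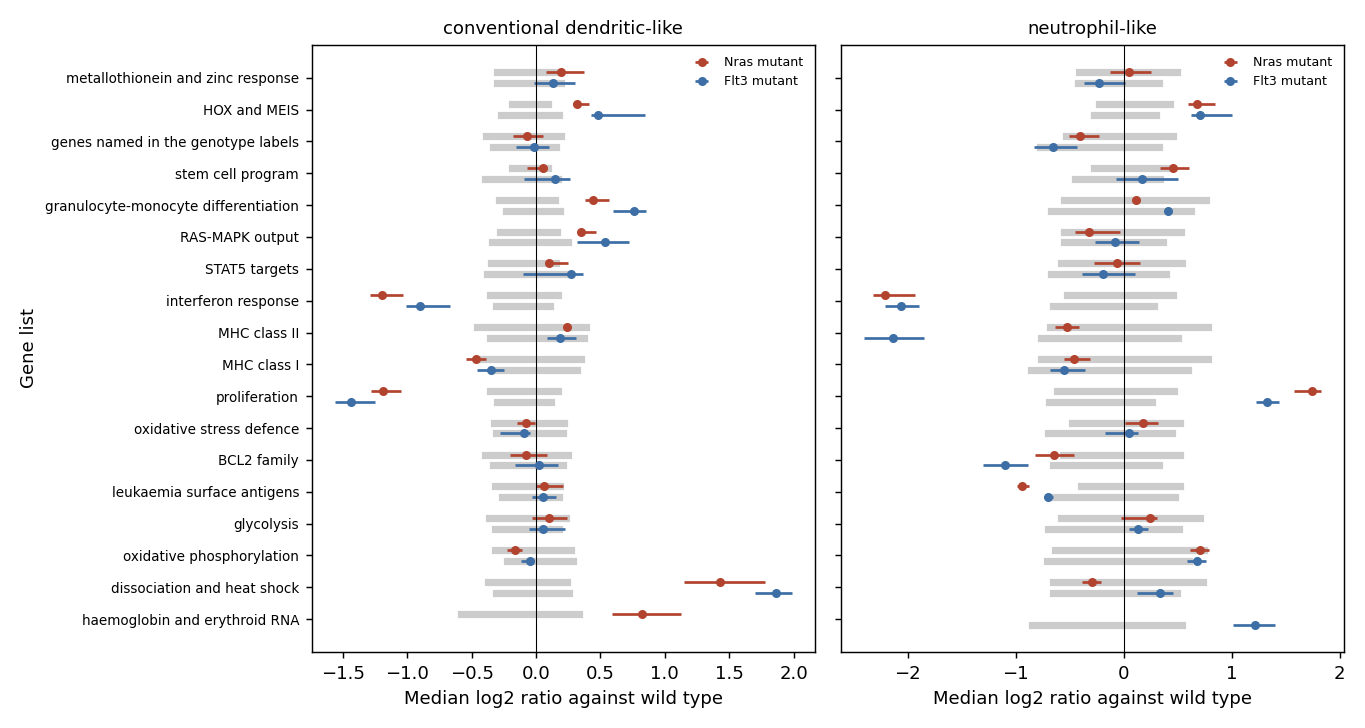
Median log2 ratio against wild type for each gene list in conventional dendritic-like and neutrophil-like cells of both mutants, with bars for counting error at 95% and grey bands for the middle 95% of random lists. Interferon response lay below its band in all 4 comparisons (−1.20, −0.90, −2.21 and −2.06), and proliferation lay below it in dendritic-like and above it in neutrophil-like cells.

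Neutrophil-like cells were compared next. Both mutants had higher RNA of Mt1, of Hoxa9, of the primary granule genes Prtn3 and Elane, and of proliferation genes. Wild-type cells had higher RNA of Il1b and of interferon response genes. Mt1 was at 308 CPM (295 to 321) in the Nras mutant, 238 (227 to 249) in the Flt3 mutant and 10.8 (6.48 to 16.8) in wild type, or 28.6-fold (18.3 to 47.6) and 22.1-fold (14.1 to 36.8) higher. Hoxa9 was at 76.5 and 58.4 CPM with 0 wild-type UMIs, at least 45.0-fold and 34.4-fold higher. Hoxa10 was at least 22.6-fold and 17.7-fold higher (38.5 and 30.01 CPM), and Hoxa7 at least 18.97-fold and 13.2-fold higher (32.2 and 22.4 CPM), both with 0 wild-type UMIs. Mt2 was at 7.87, 6.35 and 1.13 CPM. Dnmt3a was at 7.43, 2.16 and 21.5 CPM, and Npm1 at 268, 223 and 116.7. The Flt3 mutant ratio of Npm1 (0.88) turned to −0.34 in matched clusters and to −0.12 with doublets kept.

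The higher genes in neutrophil-like cells included primary granule genes. Elane and Prtn3 are leading genes of cluster 22, which held 167 of 367 Nras mutant and 134 of 470 Flt3 mutant cells but 7 of 301 wild-type cells. In the Nras mutant, the Flt3 mutant and wild type, Ctsg was at 785, 567 and 3.96 CPM, Prtn3 at 1505, 1842 and 69.1, Elane at 796, 1846 and 86.6, Mpo at 227, 270.4 and 18.7, and Ms4a3 at 536, 609 and 37.9. Ctsg was at 7153 and 5874 CPM in progenitor-like cells of the same mutant libraries. Free RNA of those cells could give up to 29.7% of Ctsg in the Nras mutant. In the Flt3 mutant Ctsg itself sets the bound, so free RNA could give all of it, and up to 39.2% of Prtn3, 52.4% of Elane and 46.8% of Mpo. In cluster 16 alone the log2 ratios were 6.08 and 4.48 for Ctsg, 4.78 and 4.34 for Prtn3, 3.33 and 3.59 for Elane, and 4.003 and 2.38 for Mpo. Fosb was at 95.5, 137 and 3.40 CPM, Dut at 240.4, 176 and 18.1, Lipg at 71.3, 89.1 and 3.96, and the cell-cycle inhibitor gene Cdkn2c at 97.3, 90.9 and 7.36. The chemokine gene Cxcl2 had 1 wild-type UMI, and was 83.4-fold (14.9 to 3305) and 188-fold (33.6 to 7430.2) higher. Lower in both mutants were Pla2g7 (0.297, 0.811 and 478 CPM), Ifi27l2a (2.23, 9.60 and 812), Il1b (19.2, 53.9 and 1694) and Ifitm1 (14.6, 20.4 and 514). Amica1 was at 5.05, 4.46 and 262 CPM, Cd300ld at 6.39, 5.81 and 271, Gcnt2 at 9.80, 13.9 and 380.0, and Marcks at 32.4, 23.8 and 668. Il1b and Pla2g7 are leading genes of cluster 27, which held 225 wild-type cells and 1 mutant cell. In cluster 16, shared by all libraries, the ratios of Il1b went from −5.87 and −4.74 to −1.75 and −0.80, and those of Ifitm1 from −4.42 and −4.11 to −0.37 and −0.26. Cd79a (0, 0 and 232 CPM) and Ly6d (0, 0 and 163 CPM), which B cells express, were at least 521-fold and 366-fold lower in the Nras mutant. Lars2 was at 77.7, 114 and 2445 CPM, and was higher in the wild-type library as a whole.

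Among gene lists in neutrophil-like cells, interferon response was at −2.21 and −2.06 (both percentile 0), with all 17 members lower in both mutants. Isg15 was at 2.23, 8.11 and 129 CPM, and Irf7 at 3.27, 4.06 and 65.1. Proliferation was at 1.75 and 1.33 (both percentile 100), with all 20 genes higher, and Pcna was at 134, 87.9 and 18.1 CPM. In cluster 16 the proliferation medians were 1.16 and 0.84. HOX and MEIS was at 0.68 and 0.71 (0.51 and 0.65 with genes of 0 UMIs at their bound). With pseudocounts of 1 and 50 CPM the HOX and MEIS median was 2.77 and 0.18 in the Nras mutant and 2.88 and 0.24 in the Flt3 mutant, and the interferon response median was −3.95 and −0.87, and −3.61 and −0.95. MHC class II was at −0.52 (percentile 6.52, and −1.94 in matched clusters) in the Nras mutant and −2.14 (percentile 0) in the Flt3 mutant, with Cd74 at 479, 14.5 and 1189.9 CPM. The wild-type cells alone had RNA of the B-cell genes Cd79a and Ly6d, and B cells also express class II genes, so part of this difference may be B-cell RNA. BCL2 family was at −0.64 and −1.10, with Mcl1 at 294, 198 and 838 CPM, and both medians were −0.11 in matched clusters. Leukaemia surface antigens was at −0.94 and −0.70, with Cd44 at 81.7, 121 and 644 CPM and Clec12a at 633, 459 and 237. All 18 oxidative phosphorylation genes were higher in both mutants (0.71 and 0.68, percentiles 96.8 and 98.4), but the Nras mutant median lay within the middle 95% of random lists (−0.64 to 0.75). The stem cell program was at 0.46 and 0.18, granulocyte-monocyte differentiation at 0.11 and 0.41, glycolysis at 0.24 and 0.14, oxidative stress defence at 0.18 and 0.05 (the second −0.10 in matched clusters), and metallothionein and zinc response at 0.05 and −0.22. Genotype-label genes were at −0.40 and −0.66, MHC class I at −0.46 and −0.55, and STAT5 targets at −0.06 and −0.19. RAS-MAPK output was at −0.32 and −0.08, which turned to 0.11 in matched clusters and to 0.21 with TMM scaling. Dissociation and heat shock was at −0.29 and 0.34, and the first turned to 1.23 in matched clusters. Haemoglobin and erythroid RNA was at 1.22 in the Flt3 mutant.

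In cluster 16 (200, 335 and 69 cells) Mt1 was 38.7-fold (17.7 to 106) and 18.0-fold (8.23 to 49.3) above wild type, Hoxa9 at least 16.0-fold and 10.96-fold, and the interferon response medians were −1.49 and −1.35. Same-side genes were 86.7% of 8097, against 79.6% in draws without a difference. Those draws hold only the counting error of the shared control, so part of the excess may come from what is particular to that 1 library. The smallest ratio named was 2.44 in size, against 0.79 for the largest in those draws, which again speaks to counting error alone. Median depths were 17516, 14364.5 and 3427 UMIs, and TMM scaling changed the Flt3 mutant ratios by 0.34 before the pseudocount.

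Between the mutants, the Nras mutant neutrophil-like class had higher class II RNA, part of which may come from dendritic-like cells, and Flt3 mutant cells had higher RNA of Stfa1, Stfa2 and Stfa3. Cd74 was at 479 against 14.5 CPM (log2 ratio 4.32), H2-Aa at 251 against 8.11, H2-Ab1 at 237 against 7.30 and H2-Eb1 at 247 against 9.19. By the marker Xcr1, free RNA of dendritic-like cells, which were 47.0% and 6.43% of the libraries, could give up to 29.0% of the Cd74 and 32.9% of the H2-Ab1 level in the Nras mutant. Dendritic-like cells misplaced in this class were not tested. The cell-cycle inhibitor gene Cdkn1c was at 137 against 10.7 CPM, Hist1h2bl at 154 against 17.3, H1f0 at 142 against 22.2 and Ikzf2 at 58.1 against 7.17. Lower were Stfa2 (4.31 against 366 CPM), Stfa1 (43.4 against 1331), Stfa3 (2.38 against 263), BC100530 (63.6 against 1617) and Stfa2l1 (70.4 against 397), which are close paralogs whose reads can be shared. Hspa1b was at 1.63 against 60.4 CPM, Acot1 at 1.04 against 48.0 and Mmp8 at 39.2 against 182. Mt1 was 0.36 higher in the Nras mutant, and this turned to −0.69 with each library clustered on its own. There, Hoxa9 went from 0.34 to −0.05, Dnmt3a from 0.52 to −0.05 and Npm1 from 0.25 to −1.25. The MHC class II list was at 1.10 (percentile 100), dissociation and heat shock at −0.37 (percentile 0), and interferon response at −0.09, or 0.29 with at least 100 UMIs per gene. TMM scaling changed these ratios by −0.25 before the pseudocount.

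Monocyte-like cells could be compared for the Flt3 mutant and wild type (173 and 244 cells, all in cluster 18). Mt1, Hoxa9, Hoxa7 and Hoxa10 were higher in the Flt3 mutant, and interferon response genes and most class II genes were lower. Mt1 was at 238 CPM (215 to 263) against 10.4 (6.84 to 15.1), or 22.95-fold (15.5 to 35.3). Hoxa9 was at 36.3 CPM against 0 UMIs, at least 31.5-fold higher, Hoxa7 at least 29.4-fold and Hoxa10 at least 22.4-fold. Mt2 was at 11.7 CPM against 0 UMIs, at least 10.1-fold higher. Dnmt3a was at 6.16 against 28.8 CPM. The B-cell genes Cd79a (0 against 165 CPM), Ly6d (0 against 109.6) and Ms4a1 (0 against 76.2), chosen after their values were seen, had UMIs in the wild-type cells alone, and B cells also express class II genes. Npm1 was at 649 against 570.4 CPM, and its ratio of 0.18 turned to −0.16 at Leiden resolution 0.5. The interferon list was at −1.75 with all 18 genes lower (percentile 0), where Isg15 was at 4.93 against 167 CPM and Irf7 at 16.6 against 173. HOX and MEIS was at 1.08 (2.61 and 0.37 with pseudocounts of 1 and 50 CPM), with 4 members higher and 2 lower, among them Hoxb4 at 8.62 against 12.7 CPM. MHC class II was at −1.19, with 7 members lower and 2 higher, H2-Oa (14.8 against 11.2 CPM) and H2-Ob (23.4 against 20.001). Proliferation was at −0.74, dissociation and heat shock at 1.13, glycolysis at 0.58 and oxidative stress defence at 0.43. TMM scaling changed these ratios by 0.17 before the pseudocount, and median depths were 8628 and 10368 UMIs.

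Genes of the Y chromosome divided the Flt3 mutant library. Summed RNA of Ddx3y, Eif2s3y, Uty and Kdm5d was at 155 CPM (151 to 158) in Nras mutant progenitor-like cells and 114 (94.2 to 136) in the 21 wild-type ones. In the Flt3 mutant, progenitor-like clusters 5, 11, 13, 15, 21, 23 and 24 (4957 cells, 91.9% of the class) were at 0.324 CPM. Clusters 7, 12, 20 and 25, the ones shared with the Nras mutant (435 cells, 8.07%), were at 136 CPM. With cells thinned to 5000 UMIs, 0 to 0.368% of cells per cluster had a Y-linked UMI in the first set and 46.8 to 53.6% in the second. Without thinning these shares were 0.247 to 2.91% and 86.0 to 100%. Median depths ran from 25722 to 40413 and from 16332.5 to 40496.5 UMIs. In other classes of the Flt3 mutant, Y-linked RNA was at 87.1 CPM in conventional dendritic-like, 15.4 in neutrophil-like, 21.6 in monocyte-like and 27.1 in plasmacytoid dendritic-like cells. It was at 134 CPM in the 177 cells of unnamed clusters 2 and 6, which held 1762 and 1088 Nras mutant cells. Conventional dendritic-like cells of the Nras mutant and wild type were at 140.5 and 145 CPM.

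**Figure D4:**
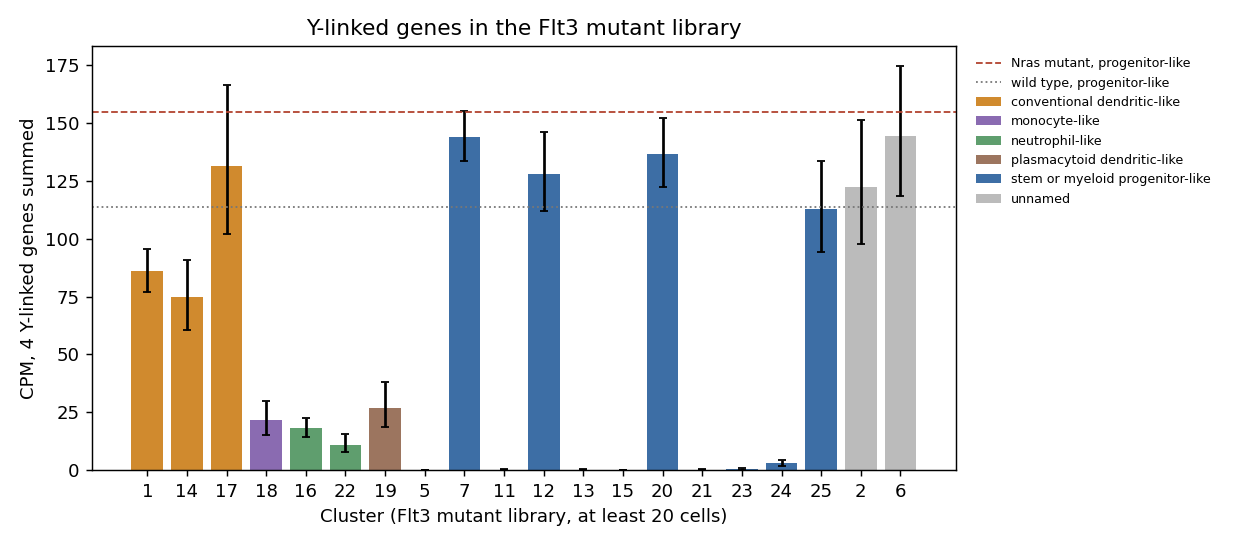
Summed CPM of 4 Y-linked genes in each Flt3 mutant cluster with at least 20 cells, coloured by class, with 95% Poisson bars; lines mark progenitor-like cells of the Nras mutant and wild type. Clusters 7, 12, 20 and 25 were between 113 and 144 CPM, and the other progenitor-like clusters were at 3.06 CPM or less.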

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

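The tests of free RNA, of matched clusters and of the dissociation response were chosen only after the results were seen; the question of animal or preparation was set before. Values stood out for 2 reasons: opposite directions in the 2 mutants, and signal in cells that no comparison used. With 1 library per genotype, none of the differences between groups was tested.

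The Flt3 gene in conventional dendritic-like cells had a log2 ratio of −0.40 in the Nras mutant and 0.20 in the Flt3 mutant, both against wild type. The dissociation and heat shock list in neutrophil-like cells was at −0.29 in the Nras mutant and 0.34 in the Flt3 mutant. These were noted because the directions were opposite. The list medians lay within the middle 95% of their random lists (percentiles 15.9 and 92.4), and in matched clusters they were 1.23 and 1.21, no longer opposite.

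Cells outside the comparisons also carried Mt1 and Hoxa9 RNA in the mutants. In 2858 Nras mutant cells of unnamed clusters Mt1 was at 305 CPM and Hoxa9 at 84.2 CPM. In 177 Flt3 mutant cells of unnamed clusters they were at 82.5 and 81.1 CPM. The 33 wild-type cells of unnamed clusters had Mt1 at 26.8 CPM and no Hoxa9 UMI, which allows up to 3.35 CPM. They are not a like baseline, since 30 of them lay in cluster 33, which scored highest for plasma cell markers. The mutant cells lay mostly in clusters 2 (1762 Nras mutant and 95 Flt3 mutant cells) and 6 (1088 and 82). Those clusters scored highest for conventional dendritic markers. In 153 plasmacytoid dendritic-like cells of the Flt3 mutant Mt1 was at 212 CPM and Hoxa9 at 59.9 CPM, against 4.58 and 2.29 CPM in 256 wild-type cells.

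The pattern weighed here is that Mt1 and Hoxa9 were higher in both mutants than in wild type in conventional dendritic-like and neutrophil-like cells. Free RNA from progenitor-like cells was bounded by the progenitor marker with the lowest level in the class, and could give at most 3.34% of the observed level in conventional dendritic-like cells and 32.6% in neutrophil-like cells, so the tables argue against it as the whole cause. Different clusters of each class are argued against as well, since the smallest Mt1 log2 ratio within matched clusters was 2.61 and the lowest fold bound 6.04, or 2.53 in single dendritic-like clusters. The 2.61 and 6.04 come from Flt3 mutant cells of dendritic-like clusters 14 and 17, part of which may come from another animal or sample. In dendritic-like cells of the Nras mutant the matched ratio was 3.46 and its fold bound 11.6. A response to dissociation in the mutant libraries stays open and cannot be told apart: the list was at −0.29 in neutrophil-like cells of the Nras mutant (percentile 15.9), but within matched clusters its lowest median was 1.12. Animal or library preparation rather than genotype cannot be told apart either, because there was 1 wild-type library, and an effect of the genotypes remains a hypothesis.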

How the results depend on the processing

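Matched clusters, and the Leiden resolutions for ratios, were chosen only after the results were seenand the other settings were fixed before the data were examined. Each genotype was 1 library, so no leave-one-out or other split was possible. No paired analysis was possible because no label pairs the libraries. The cause was not tested for any value below. A turn is listed only where the main value had a direction: its counting interval excluded 0 and, for a list, its median lay outside the middle 95% of random lists. Turns of other values are counted at the end. The progenitor-like share of Nras mutant cells (%) was 21.1, and 18.1 with no cell filter, 20.01 with doublets kept, 18.8 with Leiden resolution 0.5, 17.2 with Leiden resolution 2 and 16.8 with each library clustered on its own. The progenitor-like share of Flt3 mutant cells (%) was 79.1, and 78.1 with the stricter filter, 73.2 with no cell filter, 77.8 with Leiden resolution 0.5, 77.5 with Leiden resolution 2 and 78.1 with each library clustered on its own. The progenitor-like share of wild type cells (%) was 0.229, and 0.369 with the stricter filter and 0 with each library clustered on its own.

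Mt1 in progenitor-like cells, Nras against Flt3 mutant (−0.18), was −0.34 with TMM scaling, −0.23 with the mean of per-cell CPM, −0.26 with thinned cells, −0.24 with the total without abundant classes, −0.38 with doublets kept, −0.12 with each library clustered on its own, −0.35 with Leiden resolution 0.5, −0.13 with Leiden resolution 2 and 0.80 with matched clusters (opposite direction). Mt1 in dendritic-like cells, Nras mutant (3.97), was 4.56 with a pseudocount of 1 CPM, 2.75 with a pseudocount of 50 CPM, 3.30 with the mean of per-cell CPM, 3.32 with thinned cells and 3.46 with matched clusters. HOX and MEIS in dendritic-like cells, Nras mutant (0.32), was 1.69 with a pseudocount of 1 CPM and 0.069 with a pseudocount of 50 CPM. For genes of interferon response the median in dendritic-like cells, Nras mutant (−1.20), was −2.05 with a pseudocount of 1 CPM, −0.50 with a pseudocount of 50 CPM and −0.80 with matched clusters. Mt1 in dendritic-like cells, Flt3 mutant (2.16), was 2.67 with a pseudocount of 1 CPM, 1.24 with a pseudocount of 50 CPM, 1.53 with the mean of per-cell CPM, 1.67 with thinned cells and 2.61 with matched clusters. HOX and MEIS in dendritic-like cells, Flt3 mutant (0.48), was 2.20 with a pseudocount of 1 CPM, 0.14 with a pseudocount of 50 CPM, 0.42 with no UMI minimum, 1.63 with at least 100 UMIs and 1.79 with matched clusters. For genes of interferon response the median in dendritic-like cells, Flt3 mutant (−0.90), was −1.17 with a pseudocount of 1 CPM, −0.35 with a pseudocount of 50 CPM, −1.01 with no UMI minimum, −0.55 with at least 100 UMIs and −0.65 with matched clusters. Mt1 in dendritic-like cells, Nras against Flt3 mutant (1.81), was 1.51 with a pseudocount of 50 CPM, 1.65 with thinned cells, 1.67 with each library clustered on its own, 1.70 with Leiden resolution 2 and 1.14 with matched clusters. Mt1 in neutrophil-like cells, Nras mutant (3.94), was 4.71 with a pseudocount of 1 CPM, 2.56 with a pseudocount of 50 CPM, 4.53 with the mean of per-cell CPM, 4.62 with thinned cells, 4.39 with doublets kept and 4.34 with Leiden resolution 0.5. HOX and MEIS in neutrophil-like cells, Nras mutant (0.68), was 2.77 with a pseudocount of 1 CPM, 0.18 with a pseudocount of 50 CPM, 0.38 with no UMI minimum, 2.06 with at least 100 UMIs and 1.79 with matched clusters. For genes of interferon response the median in neutrophil-like cells, Nras mutant (−2.21), was −3.95 with a pseudocount of 1 CPM, −0.87 with a pseudocount of 50 CPM, −1.88 with no UMI minimum, −2.49 with at least 100 UMIs and −1.49 with matched clusters. Mt1 in neutrophil-like cells, Flt3 mutant (3.58), was 4.34 with a pseudocount of 1 CPM, 2.24 with a pseudocount of 50 CPM, 4.25 with thinned cells, 4.54 with each library clustered on its own and 3.001 with matched clusters. HOX and MEIS in neutrophil-like cells, Flt3 mutant (0.71), was 2.88 with a pseudocount of 1 CPM, 0.24 with a pseudocount of 50 CPM, 0.60 with no UMI minimum, 1.70 with at least 100 UMIs and 1.11 with matched clusters. For genes of interferon response the median in neutrophil-like cells, Flt3 mutant (−2.06), was −3.61 with a pseudocount of 1 CPM, −0.95 with a pseudocount of 50 CPM, −2.44 with at least 100 UMIs and −1.35 with matched clusters. Mt1 in neutrophil-like cells, Nras against Flt3 mutant (0.36), was 0.11 with TMM scaling, 0.68 with the mean of per-cell CPM, 0.45 with the stricter filter, 1.00 with doublets kept, −0.69 with each library clustered on its own (opposite direction) and 1.04 with Leiden resolution 0.5. Mt1 in monocyte-like cells, Flt3 mutant (3.61), was 4.39 with a pseudocount of 1 CPM, 2.26 with a pseudocount of 50 CPM, 4.01 with the total without abundant classes, 3.93 with the stricter filter and 3.32 with Leiden resolution 2. HOX and MEIS in monocyte-like cells, Flt3 mutant (1.08), was 2.61 with a pseudocount of 1 CPM, 0.37 with a pseudocount of 50 CPM and 0.24 with no UMI minimum. For genes of interferon response the median in monocyte-like cells, Flt3 mutant (−1.75), was −3.03 with a pseudocount of 1 CPM and −0.78 with a pseudocount of 50 CPM.

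Matched clusters turned these values to the opposite direction or 0: in progenitor-like cells, Nras against Flt3 mutant, Ly6k −0.31, Clu 0.11, Wdr66 0.092, Hoxa9 −0.32, Hoxa10 −0.86, Hoxa7 −0.18, Dnmt3a −0.10, genes named in the genotype labels −0.018, stem cell program −0.22, granulocyte-monocyte differentiation 0.31, interferon response −0.035 and leukaemia surface antigens −0.077; in dendritic-like cells, Nras mutant, haemoglobin and erythroid RNA −0.73; in dendritic-like cells, Flt3 mutant, Egr1 −0.34; in dendritic-like cells, Nras against Flt3 mutant, haemoglobin and erythroid RNA −0.015; in neutrophil-like cells, Flt3 mutant, Npm1 −0.34. TMM scaling turned these values to the opposite direction or 0: in progenitor-like cells, Nras against Flt3 mutant, Mt2 −0.080; in dendritic-like cells, Nras mutant, Npm1 0.12. The mean of per-cell CPM turned these values to the opposite direction or 0: in progenitor-like cells, Nras against Flt3 mutant, Mt2 −0.082; in neutrophil-like cells, Nras against Flt3 mutant, Meis1 0.022. Thinned cells turned these values to the opposite direction or 0: in progenitor-like cells, Nras against Flt3 mutant, Mt2 −0.098; in dendritic-like cells, Nras mutant, Npm1 0.14; in dendritic-like cells, Flt3 mutant, Meis1 −0.12 and Npm1 0.11. Doublets kept turned these values to the opposite direction or 0: in progenitor-like cells, Nras against Flt3 mutant, Mt2 −0.13; in neutrophil-like cells, Flt3 mutant, Npm1 −0.12. Leiden resolution 0.5 turned these values to the opposite direction or 0: in progenitor-like cells, Nras against Flt3 mutant, Mt2 −0.14; in monocyte-like cells, Flt3 mutant, Npm1 −0.16. The stricter filter turned these values to the opposite direction or 0: in dendritic-like cells, Nras mutant, Il4i1 0.000691 and Fabp5 0.21; in dendritic-like cells, Flt3 mutant, Il4i1 0.028 and Fabp5 0.43. Each library clustered on its own turned these values to the opposite direction or 0: in dendritic-like cells, Nras mutant, Fscn1 0.025 and Fabp5 0.35; in dendritic-like cells, Flt3 mutant, Fscn1 0 and Fabp5 0.22; in neutrophil-like cells, Nras against Flt3 mutant, Hoxa9 −0.045, Dnmt3a −0.047 and Npm1 −1.25. No UMI minimum turned these values to the opposite direction or 0: in dendritic-like cells, Flt3 mutant, RAS-MAPK output 0. At least 100 UMIs turned these values to the opposite direction or 0: in neutrophil-like cells, Nras against Flt3 mutant, interferon response 0.29.

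Of the values for named genes other than Mt1, 1181 stayed within their counting interval, 1139 moved beyond it and 32 turned from a main value with a direction, and for gene lists other than the main lists these were 482, 294 and 9. For Mt1 they were 50, 44 and 2. The main lists had 20 and 39, with no such turn. All 204 gene ratios kept their direction with Leiden resolution 2, with either pseudocount and with the total without abundant classes, and 194 did in matched clusters. With thinned cells 7 did not keep it (4 with a direction), with each library clustered on its own 9 (8) and with the mean of per-cell CPM 3 (2). Counting all list medians, with or without a direction, 18 of 141 did not keep their sign with TMM scaling (0 of them with a direction) and 26 of 141 did not in matched clusters (7 with a direction). For 139 medians with at least 100 UMIs and 141 with no UMI minimum these were 8 and 10 (1 each with a direction), and with a pseudocount of 1 CPM all kept their sign. Depth limited the neutrophil-like comparison most: thinning to 3000 UMIs left out 96 of 301 wild-type cells.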

Other observations

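All tests of the Y-linked pattern were chosen only after the result was seen; the tests of the interferon response list were set before that result was seen, although matched clusters were added as a setting, and single clusters as a test, after the data were seen.

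Y-linked genes were near 0 in most progenitor-like clusters of the Flt3 mutant library and present in the others. Low depth of the cells is argued against, since in thinned cells the highest share with a Y-linked UMI among the low clusters was 0.368% and the lowest among the others 46.8%. Barcodes of the Nras mutant library read in the Flt3 mutant library are argued against too: 0.460% of the cells in the clusters with Y-linked RNA, 2 of 435, carried an Nras mutant barcode. Cells of a female animal do not go with Xist at 0.0198 CPM in the low clusters (upper bound 0.0580), although no female library was at hand to show that Xist would be seen. The values go with the hypothesis of no Y chromosome in the cells of these clusters. The highest of the 4 genes there was at 0.242% of its Nras mutant level. Cells of more than 1 animal in the pool, or physical mixing of samples, could also divide the library and were not tested. By themselves they leave open why Y-linked RNA and Xist were both near 0 in the low clusters, unless Xist of female cells goes unseen here.

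In conventional dendritic-like and neutrophil-like cells the interferon response list was lower in both mutants than in wild type. Different clusters of each class are argued against as the whole cause, since the median closest to 0 within matched clusters was −0.65. It came from Flt3 mutant cells of dendritic-like clusters 14 and 17, part of which may come from another animal or sample. Within single dendritic-like clusters the median closest to 0 was −0.349, in cluster 17 of the Nras mutant (counting interval −0.63 to −0.11). That value lay within the main range of random lists, whose lower limit was −0.356. The median over all Nras mutant dendritic-like cells was −1.20, so part of the difference may come from cluster makeup. Scaling to total UMIs is argued against by −0.77 with TMM scaling. Animal or library preparation rather than genotype cannot be told apart, because there was 1 wild-type library, which also stood apart in Gm42418, Lars2 and Kit. The labels mention polyI:C, an inducer of interferon, without saying which animals received it or when, so exposure of the wild-type animal stays open and untested.

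Barcodes shared between the Nras mutant and Flt3 mutant libraries numbered 17, and between the other pairs of libraries 25 to 47.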
